A study of Drosophila melanogaster with 2 samples.

How the data were processed

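The 2 libraries were ChIP-seq libraries of whole Drosophila melanogaster embryos, 0 to 24 hours old, of a transgenic line with Bicoid fused to enhanced green fluorescent protein. Per the labels, chromatin was sonicated, fragments were in the range of 200 to 800 bp, and the precipitation used an antibody against the fluorescent protein. The antibody field of the labels names bcd. Both libraries were placed in 1 group from the labels' description of the fusion protein, and the replicate numbers 1 and 3 are those of the labels, which give each library its own biosample and call the numbers biological replicates. The labels name a control experiment, which was not analysed here.

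The authors made the peak lists in narrowPeak format on 2 genome builds, dm6 and dm3, per the deposited file descriptions. For each build there were relaxed lists of peaks and background, meant as input for IDR, for each replicate and for both replicates pooled, and an IDR-thresholded optimal set derived from the replicate lists and the pooled list. The peak lists hold the authors' signal value per peak, a score on the peak caller's own scale that was used only to describe and rank peaks within a list. They also hold the authors' -log10 q value, which is tied at its highest value of 4.03 for 5376 of the 6054 IDR peaks and so was not used to rank, and the summit position. The peak caller, the aligner and their settings are not given in the sources used here. Peaks were called per replicate and on the pooled replicates, so the IDR set is not an independent average of the 2 libraries. In dm6, 6054 IDR entries made up 6000 distinct intervals, and entries with a shared interval have different summits. Because the lists hold no read counts, the depth of each library is unknown, and a weaker list cannot be told from a shallower library.

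Coordinates are dm6, counted from 1. The genome sequence and the gene annotation used (Ensembl BDGP6.54, release 115) are of the same Release 6 assembly, and all dm6 peaks lay inside its arms. No dm3 sequence was used, so dm3 lists entered only the counts and the replicate overlap. Coordinates were never converted between builds, and the builds are 2 mappings of the same reads, not replicates.

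Replicates were compared by the share of the N strongest entries of replicate 1 that overlap, by at least 1 bp, the N strongest of replicate 3, with N the number of IDR peaks, against 1000 circular shifts along each arm. A word was counted as present when it occurred on either strand in the 201 bp around a summit. It was compared with windows of the same size centred 1000 bp up- and downstream by an exact sign test of summit against upstream flank, and the ratio uses the mean of both flanks. The 8 other words were adjusted together. Each summit was placed in the first fitting class of near TSS (within 500 bp), coding exon, untranslated region, noncoding exon, intron and intergenic, and compared with 1000 shifts. Shifts also move summits into repeat-rich sequence, where peaks are rare. For 20 gene lists, the number of protein-coding genes with an IDR summit in the gene or the 5 kb upstream was compared with 10000 random lists matched on the decile of that window's length, in each direction, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. All list symbols were found in the annotation, 3 of them under their current names (hry for h, nanos for nos, Z600 for frs).

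The lists, tests, alternatives and the rule for named genes were fixed before the data were examined, from the literature on fly development. The rule names the genes of the 10 peaks with the highest signal, every Bicoid target, up to 3 members with the highest signal in each other list, and bcd. The alternatives changed the overlap that counts as shared, the number of peaks, the build, the word, the windows and their control, the promoter width, the assignment of peaks to genes, the matching, and left out each replicate in turn. The alternatives for the replicate overlap used 200 shifts each. Alternatives for the gene lists chosen after seeing the data were the whole pooled relaxed list and, for the E(spl) complex, all runs of 11 neighbouring protein-coding genes in the same decile of summed window length. For the closing part, words were ranked by their summit to flank ratio, with 1 added to each count, among all words of the same base composition. Tests of 2 further explanations were run and then dropped from the closing part to keep its number of patterns and explanations small. One asked whether summits were placed too coarsely to show TAATCC, for which the windows of 200 bp on either side remain among the alternatives. The other asked whether extra copies of the bcd locus from the transgene raised its signal, and it could not decide. One gene among the strongest peaks of replicate 1 alone is not reported here.

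Each planned statistic was tested on simulated data. Where 30% of 2000 peaks were placed on another set, the overlap above shifts was 29.9%, and of 40 pairs of unrelated sets 0 had p under 0.05. Where TAATCC was written into 3% of 3000 random windows, 19 of 20 simulations had p under 0.05, and with none written 3 of 40 did. With 40% of 2000 summits placed at TSSs, 48.0% were found near a TSS where 48.2% was expected. A list of 20 genes, of which at least 16 were given a peak, was called in 19 of 20 simulations, and 1 of 380 random lists was called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.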

Results

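Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole embryos of Drosophila melanogaster that carried a transgene for Bicoid fused to enhanced green fluorescent protein. Bicoid, the product of the gene bcd, is a maternal homeodomain transcription factor that patterns the anterior of the embryo. The tagged protein was precipitated with an antibody against the fluorescent protein. The 2 libraries, replicates 1 and 3, came from separate biosamples of mixed-sex embryos aged 0 to 24 hours and formed 1 group, so the design holds no second condition and the comparisons are between sites, between genes and between the 2 libraries. The measurements were the authors' peak lists. On dm6 the thresholded set, made with the irreproducible discovery rate (IDR) procedure, held 6054 peaks with a median width of 424 bp, and each replicate's relaxed list held 30000 entries. The lists give no read counts, so the depth of each library is unknown.

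Most of the 10 strongest peaks lay near a transcription start site (TSS). The highest signal value, 4627, belonged to the peak at X:2703661 to 2704119, whose summit lay 39 bp from the TSS of Ugalt, a UDP-galactose transporter gene. The next was at 3L:19590403 to 19590833, 93 bp from the TSS of CG14100, with a signal of 4334. The third, at 2L:480848 to 481304 with a signal of 4224, lay in an intron of ush, which encodes a cofactor of GATA factors, and 1368 bp from the TSS of cbt. The fourth was in an intron of CG11050 at 2L:6612457 to 6612954, with a signal of 4039. The other 6 of the 10 strongest peaks belonged to Chro, which encodes a chromosomal protein (signal 3105), mRpL41, a mitochondrial ribosomal protein gene (3071), px (2993), the noncoding RNA gene lncRNA:Vinr (2869), the Polycomb-group gene ph-p (2858) and Tcs5 (2843). Of the 10, the peaks of Ugalt, CG14100, Chro, mRpL41, px, ph-p and Tcs5 were within 500 bp of a TSS. The Ugalt peak ranked 1 in both replicates, and the px peak had the ranks 22 in replicate 1 and 5 in replicate 3.

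Promoters were the main location of the whole set. Of the 6054 IDR summits, 2848 (47.0%) lay within 500 bp of an annotated TSS, against 13.5% ± 0.618 (SD over 1000 circular shifts of the summits along each arm), a 3.48-fold excess. Coding exons held 13 summits (0.215%, against 13.9% after shifts), untranslated regions 83 (1.37%, against 5.02%) and intergenic sequence 832 (13.7%, against 27.2%). These 4 classes differed from the shifts with p = 0.002, the smallest that 1000 shifts can give in a two-sided permutation test (adjusted p = 0.003 over 6 classes). Introns held 2220 summits (36.7%, against 39.6%, permutation adjusted p = 0.0048), and exons of noncoding genes held 58 (0.958%, against 0.795%, adjusted p = 0.226). Without replicate 1 the intron share no longer differed from the shifts (permutation adjusted p = 0.513). The excess at promoters was highest among the strongest peaks, where 59.8% (Wilson 95% interval 57.3 to 62.2) of the 1514 peaks with the highest signal were near a TSS, against 37.0% (34.6 to 39.4) of the 1514 lowest. Intervals cover counting error only.

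The major arms held peaks at similar densities, from 41.4 per Mb on 2R (exact Poisson 95% interval 38.9 to 44.0) to 47.7 on X (45.0 to 50.6), with 47.3 on 2L, 45.7 on 3L and 45.9 on 3R. The small chromosome 4 held 12 peaks, or 8.90 per Mb (4.60 to 15.5). The assembled part of Y held 0 peaks, which allows up to 1.01 per Mb. Read mapping and copy number of the chromosomes were not assessed.

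The 2 replicates shared most of their strongest sites and differed in the weight given to promoters. Of the 6054 strongest entries of replicate 1, 70.7% overlapped the 6054 strongest of replicate 3, against 3.09% ± 0.264 (SD) after shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction the share was 69.7%. Entries strong in a single replicate were those among its 6054 strongest that overlapped none of the 6054 strongest of the other. Those of replicate 1 alone were mostly at promoters, among them those near Rpn6 and ave, HPS1 and RpS27A. The RpS27A site had no entry in the list of replicate 3, yet its pooled signal was 586 against 248 in replicate 1. A missing entry thus need not mean a weak site. Of the peaks of replicate 1 alone, 527 overlapped no entry of replicate 3 at all, and 75.7% of these were near a TSS. For replicate 3 alone these values were 359 and 26.5%. Those of replicate 3 alone were mostly in introns or between genes, such as those in CG6959 and rib, and they included a promoter peak of E(spl)m7-HLH. Near-TSS summits made up 59.5% of the 1776 peaks of replicate 1 alone and 18.8% of the 1834 peaks of replicate 3 alone, an odds ratio of 6.34 (Fisher's exact test, adjusted p = 4.06e-143 over 3 classes). Introns held 27.9% and 50.6%, and intergenic sequence 9.23% and 27.6%. This split by replicate, and the genes named for it, were chosen after the data were seen, and its p compares these 2 libraries only. Peaks are not independent replicates.

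**Figure D1:**
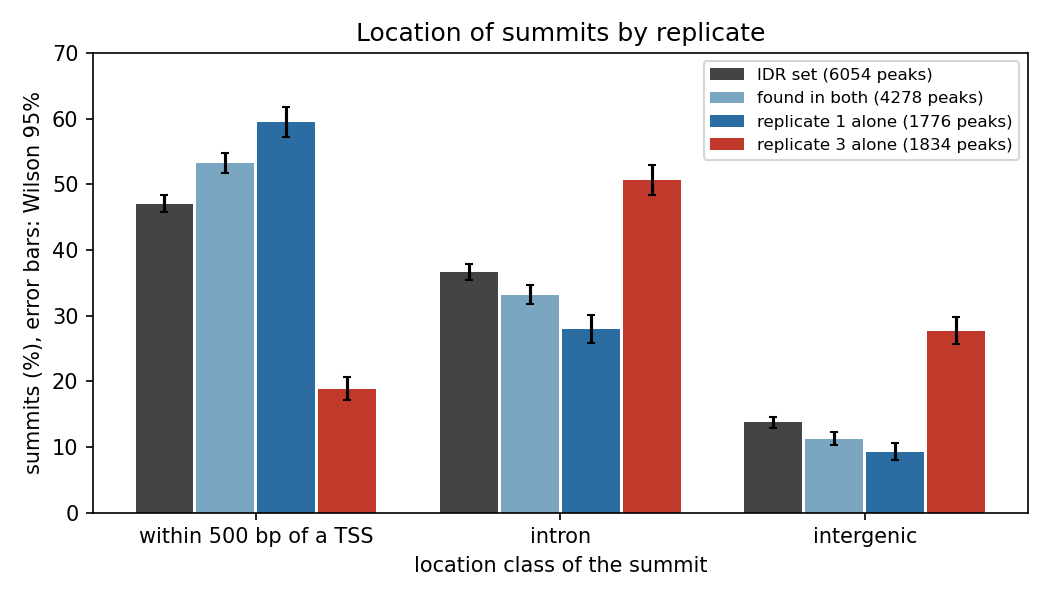
Share of summits (y axis, percent, error bars are Wilson 95% intervals) in 3 location classes (x axis) for the IDR set, for the strongest entries of replicate 1 that overlap those of replicate 3, and for the strongest entries of each replicate alone. Near-TSS summits make up 59.5% of the peaks of replicate 1 alone and 18.8% of those of replicate 3 alone.

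The IDR set was the strongest part of the pooled list. All 6054 IDR peaks were identical to pooled entries, and they were the 6054 strongest of them. Of these, 4965 (82.0%) overlapped the strongest entries of replicate 1, 5243 (86.6%) those of replicate 3, 4190 (69.2%) both, and 36 (0.595%) neither. Over the 5836 IDR peaks with an entry in both replicates' lists, the signal values had a Spearman rho of 0.593 and, on the log2 scale, a Pearson r of 0.652. The peaks were selected on the pooled signal, which in the strongest peaks is close to the sum of the 2 replicates' signals. Selection on a sum lowers the correlation of its parts, so bins of pooled signal, where rho was negative in all but the strongest, do not measure agreement. This correlation is across peaks, which are not independent replicates. On dm3, the older build, the IDR set held 5787 peaks, of which 3974 (68.7%) overlapped the strongest entries of both replicates.

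Known Bicoid targets were not enriched near the peaks. Of 23 segmentation and head genes with known Bicoid-dependent enhancers, 9 had an IDR summit in the gene or in the 5 kb upstream, where random lists matched on window length had 11.8 ± 2.31 (SD, permutation p for more = 0.92). The gap genes hb, gt, Kr and kni had none, nor did the terminal genes tll and hkb, the head genes ems, btd and slp1, the pair-rule genes eve and run, or D, pdm2 and salm. The strongest peak of the list was upstream of slp2, a forkhead gene of the pair-rule class, at 2L:3832345 to 3832679, with rank 276 and a signal of 921. It ranked 888 in replicate 1 and 128 in replicate 3. The next were at bowl (rank 539, signal 665), which had 7 summits, cnc (rank 1993, signal 305), also with 7, and cad (rank 2648, signal 248), the posterior homeobox gene whose mRNA Bicoid represses. The remaining 5 were weak. They were nub (rank 3738, signal 189), croc (4225, 171), oc (4328, 167), knrl (4513, 162) and hry, the pair-rule gene hairy (4608, 159). The peaks at croc and nub had no entry in the list of replicate 1. Their signals in replicate 3 were 128 and 97.4, against 171 and 189 in the pooled list. As at RpS27A, a missing entry need not mean a weak site, above all at nub.

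The larger relaxed list showed no excess either. Among its 30000 pooled entries, 18 of the 23 targets had at least 1 in the window, where matched lists had 18.1 ± 1.89 (SD). These entries include background, and most genes of matched lists had one, which leaves less room for an excess. The genes gt, Kr, tll, hkb and eve had 0. The best entry for hb ranked 11391 with a signal of 66.5, and the best for kni ranked 19938. When each summit was given to its nearest TSS only, the ratio of observed to expected targets turned from 0.765 to 1.61, with an adjusted p of 0.159.

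The recognition word of Bicoid was no more frequent at the summits than beside them. TAATCC, on either strand, occurred within 100 bp of the summit in 408 of the 6054 IDR peaks (6.74%, Wilson 95% interval 6.13 to 7.40) and in 6.79% of windows of the same size 1000 bp away, a ratio of 0.993 (exact sign test against the upstream flank, p = 0.971). Among the 90 words of the same base composition TAATCC ranked 72, with a median ratio of 1.13 for the others and a highest of 2.36 for TACACT. It occurred in 7.40% of the 1514 strongest peaks and 6.21% of the 1514 weakest, with an odds ratio of 1.21 (Fisher's exact test, p = 0.22). The degenerate word TAAKCY was more frequent at summits, with a ratio of 1.23 (exact sign test, p = 4.88e-16). Of its other members, TAATCT ranked 45 of 60, TAAGCC 34 of 180 and TAAGCT 12 of 102 among words of their own composition, a comparison chosen after the data were seen. The longer TAATCCC was less frequent at summits, with a ratio of 0.81 (exact sign test, p = 0.038), as was TAATCC itself in windows of 200 bp on either side (ratio 0.87, p = 0.00747).

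The words TATCGATA and GGTCACAC, by contrast, were concentrated at the summits. TATCGATA, the word of the DNA replication-related element factor DREF, occurred in 3.63% of summit windows and 0.529% of flanks, a ratio of 6.88 (exact sign test, adjusted p = 1.69e-34 over 8 words). GGTCACAC, the word of the promoter factor M1BP, occurred in 2.59% and 0.57%, a ratio of 4.55 (exact test, adjusted p = 1.53e-17). Against relaxed summits outside the IDR set, in place of flanks, these ratios were 3.50 and 2.54. The TATA word TATAAA occurred in 35.3% and 21.9%, a ratio of 1.62 (exact test, adjusted p = 2.74e-59), and TAATTA, the word of Antennapedia-class homeodomains, in 17.4% and 12.4%, a ratio of 1.41 (exact test, adjusted p = 2.34e-13). CACACACA was rarer at summits, with a ratio of 0.653 (exact test, adjusted p = 2.22e-07). CAGGTA, the word of the early activator Zelda (ratio 0.875), GAGAGAG, that of GAGA factor (0.793), and the E-box CAGCTG (0.916) did not pass the exact test, with adjusted p of 0.552, 0.147 and 0.48, although GAGAGAG and CAGCTG passed it as rarer at summits under some alternatives. Adjustment was by Benjamini-Hochberg. The exact test used the upstream flank only. The downstream flank held CAGGTA, GAGAGAG and CAGCTG more often than the upstream one, at 4.89%, 4.26% and 9.76% against 4.21%, 3.70% and 9.04%. GGTCACAC was rarer in the strongest peaks (1.45% of 1514) than in the weakest (3.04%, Fisher's exact test, p = 0.00444, not adjusted). In the 500 strongest peaks it showed little excess over flanks (ratio 1.17, exact sign test, p = 0.804, not adjusted), where TATCGATA had a ratio of 3.71. The summits of IDR peaks were richer in A and T than their flanks, 64.1% ± 7.17 (SD over peaks) against 57.5% ± 9.37. This bears on TATAAA and TAATTA, and also on words with more G and C that were rarer at summits. Among words of their own composition TATAAA and TAATTA ranked 10 of 15 and 14 of 14. CAGGTA ranked 81 of 180, with a median ratio of 0.845 for words of its composition. CACACACA, GAGAGAG and CAGCTG were not ranked in this way, so base composition stays open for them.

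**Figure D2:**
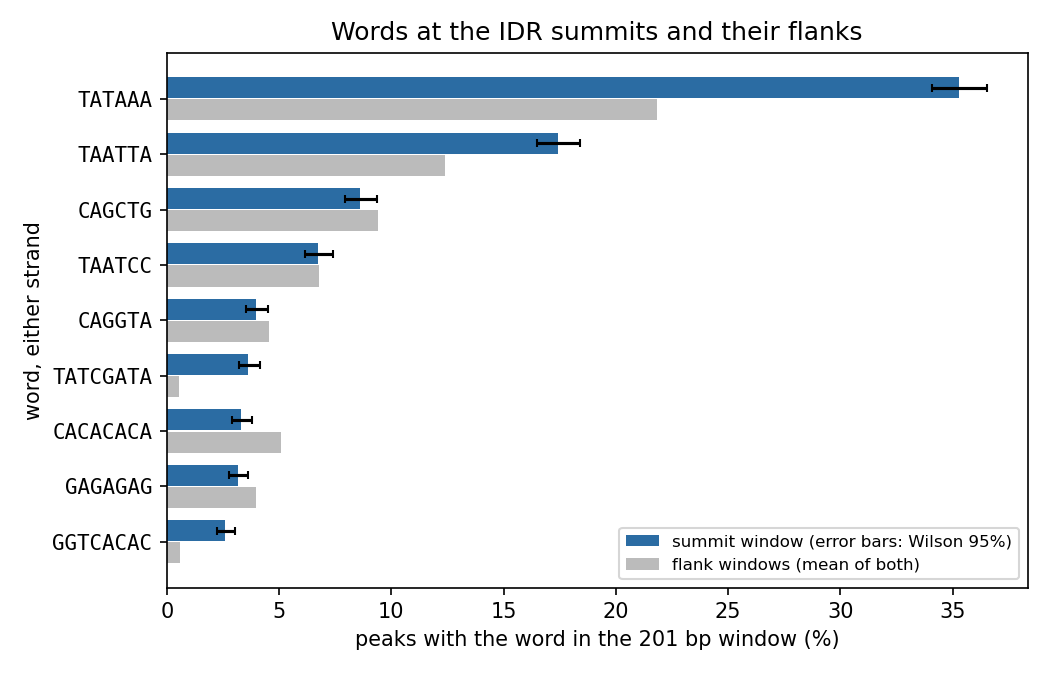
Share of the 6054 IDR peaks (x axis, percent) with each word (y axis) in the 201 bp window around the summit, with Wilson 95% intervals, and in the flank windows 1000 bp away. TAATCC stands at 6.74% and 6.79%, while TATCGATA stands at 3.63% and 0.529%.

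Most ribosomal protein genes carried peaks. Of 88 such genes, 77 had an IDR summit, against 28.8 ± 4.32 (SD) in matched lists, a 2.67-fold excess (permutation p = 0.0001, the smallest that 10000 draws can give, adjusted p = 0.002 over 20 lists). The excess was called under every alternative, but its size ranged from 1.38 with all entries of the pooled relaxed list to 4.57 with the nearest TSS only. The strongest were at RpL7 (rank 27, signal 2097), RpS27 (rank 28, signal 2081) and RpL23A (rank 73, signal 1595). The 11 without a summit, named after their values were seen, were RpL10, RpL21 and RpL29 and the paralogs or variants RpL10Aa, RpL22-like, RpL37-2, RpL7-like, RpS10a, RpS15Ab, RpS28-like and RpS28a. In the E(spl) complex, a cluster of Notch target genes on 3R, 8 of 11 genes had a summit, against 2.88 ± 1.47 (permutation adjusted p = 0.022). The 8 were 4 pairs of genes, each with the same peaks in both windows, 7 peaks in all, so the scattered genes of the random lists are a poor match. Against all 1388 runs of 11 neighbouring genes of similar summed window length, a comparison chosen after the data were seen, the ratio stayed at 2.72 against 2.78 in the main test, but the call was lost (exact test over the runs, p = 0.0958, adjusted p = 0.638). The strongest peak, at 3R:26021127 to 26021656 with rank 260 and a signal of 958, served both E(spl)m2-BFM and E(spl)m3-HLH, and the next, with rank 724 and a signal of 569, served E(spl)malpha-BFM and E(spl)mbeta-HLH. The E(spl) call was also lost without replicate 3 (ratio 1.22), where 4 genes of the complex had a summit against 8 without replicate 1, with no matching on length (ratio 1.75), with a summit within 1 kb of a TSS (ratio 2.58) and with the nearest TSS only (ratio 2.68). Odorant receptor genes carried peaks less often than matched lists, 7 of 59 against 21.9 ± 3.68 (permutation adjusted p = 0.002), the strongest being at Or88a (signal 485), Or9a (248) and Or85f (233). With all entries of the pooled relaxed list, where 34 of 59 had one, this call was lost (ratio 0.852, permutation adjusted p = 0.426).

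Lists of patterning genes did not pass the test in either direction. Among the homeotic genes 7 of 8 had a summit, against 5.35 ± 1.32 (permutation adjusted p = 0.965). Those of Antp (rank 1017, signal 468), Abd-B (rank 1037, signal 463) and Dfd (rank 2723, signal 242) were the strongest. With a summit within 1 kb of a TSS the homeotic ratio turned from 1.31 to 0.305. Of 23 dorsoventral genes 11 had a summit, led by ush (rank 3), the Dpp repressor gene brk (rank 250, signal 971) and the midline regulator sim (rank 451, signal 729). Of 9 pair-rule genes 2 had a summit, slp2 and hry. Of 10 segment polarity genes 4 did, led by nkd (signal 434), ptc (245) and inv (138). The gene Z600, an early zygotic gene, was the only 1 of 6 cellularization genes with a summit, at rank 234 and a signal of 989.

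Germ cell genes carried summits in 9 of 10 cases, against 4.96 ± 1.56, and missed the threshold (permutation adjusted p = 0.072), which they passed among the 3027 strongest peaks (ratio 2.36, adjusted p = 0.0293) and with no matching on length (ratio 2.15, adjusted p = 0.019). The ratio was lower, and not called, with a summit within 1 kb of a TSS (1.18), with all entries of the pooled relaxed list (1.17) and with the nearest TSS only (0.912). The strongest were bam (signal 2081), whose peak is the same as that of RpS27, bgcn (958) and nanos (518), the posterior determinant. Muscle genes had 9 of 18, led by the myogenic factor gene Mef2 (rank 49, signal 1805, a peak inside Pal1 and 169 bp from the TSS of Pdrg1), the tropomyosin gene Tm1 (rank 158, signal 1169) and bin (signal 981). Neuronal genes had 6 of 15, led by the neuronal RNA-binding protein gene elav (rank 105, signal 1375), the choline acetyltransferase gene ChAT (501) and the synaptobrevin gene nSyb (359). Neuroblast genes had 4 of 11, led by grh (598), pros (422) and insc (262). Gut genes had 5 of 7, led by fkh (706), cad (248) and srp (156), tracheal and epidermal genes 6 of 11, led by trh (622), CrebA (341) and bnl (274), and blood and fat body genes 3 of 11, which were ush, srp and lz (151). Heat shock genes had 5 of 12, led by Hsp27 (1418), Hsp83 (1025) and Hsp23 (470), the last sharing its peak with Hsp26. None of these lists passed the test. A peak counts for every gene whose window holds it, and many of those named lay nearest the TSS of another gene. Among them were the peaks of Tm1 (96 bp from the TSS of Cp190), nSyb (185 bp from that of Bgb), nanos (67 bp from that of CG11779) and Z600 (120 bp from that of CG7841). The ChAT peak lay 333 bp from the TSS of lncRNA:CR46265 and 14455 bp from its own. The same held for Antp, ptc, cad, pros, insc, Cpr73D, Cpr76Bb, Cpr76Bc and the odorant and gustatory receptor genes named here. In the germ cell list it also held for vas, osk, gcl, tud and aub. The neighbours were named after their values were seen.

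The other comparison lists held few peaks. Gustatory receptor genes had 15 of 60, against 22.3 expected, led by Gr61a (signal 620), Gr5a (534) and Gr32a (393). Cuticle protein genes had 15 of 70, against 23.5 expected, led by Cpr76Bb and Cpr76Bc, which share a peak with a signal of 1035, and Cpr73D (258). Chorion genes had 0 of 9, against 2.8 expected. These 3 lists had a permutation adjusted p for fewer of 0.132 each. Gustatory receptor and cuticle protein genes passed the threshold under several alternatives, and chorion genes only with no matching on length. With all entries of the pooled relaxed list cuticle protein genes turned to the other direction, 58 of 70 with an entry (ratio 1.26, permutation adjusted p for more = 0.015). In all, 5822 of 13968 protein-coding genes (41.7%) had an IDR summit in the gene or the 5 kb upstream.

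**Figure D3:**
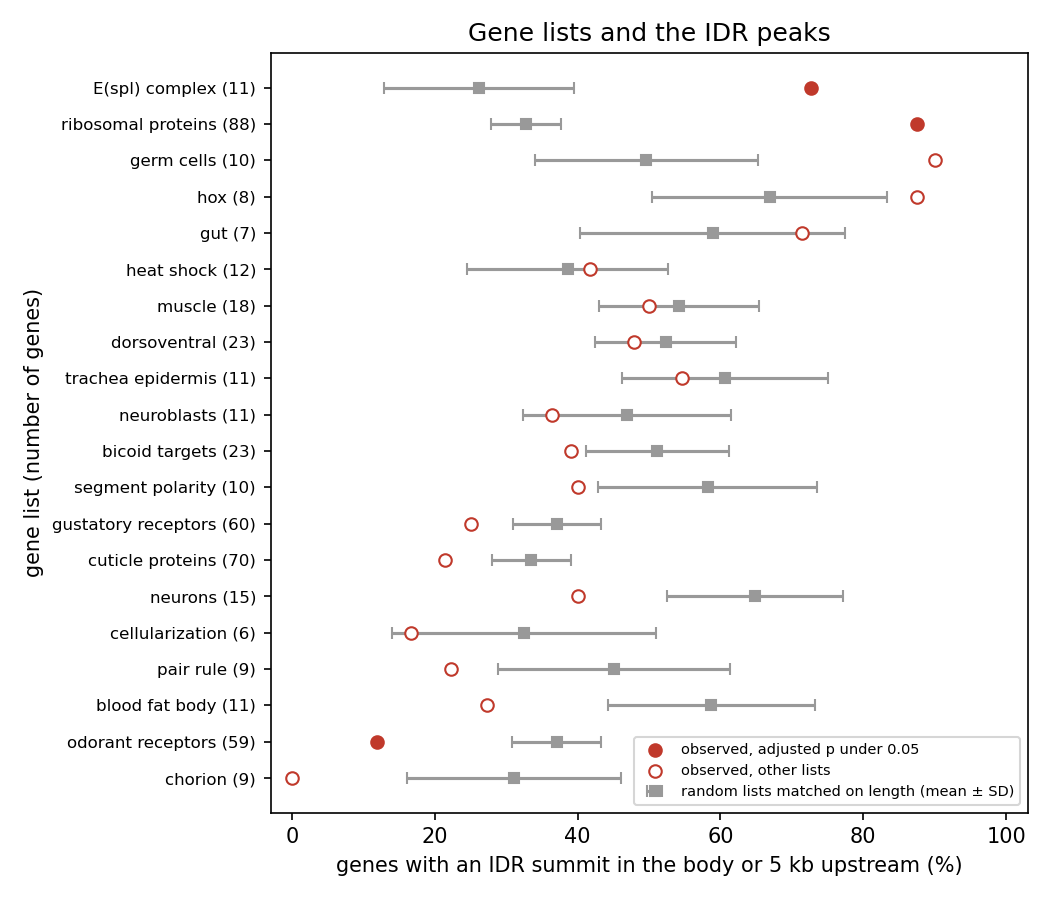
Share of the genes of each list (y axis, number of genes in parentheses) with an IDR summit in the gene or 5 kb upstream (x axis, percent). Circles are observed shares, filled where the adjusted p was under 0.05, and squares with bars are the mean and SD of 10000 random lists matched on window length. Ribosomal protein genes (77 of 88) and the E(spl) complex (8 of 11) lie above their random lists, and odorant receptors (7 of 59) lie below.

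The tagged gene itself had a peak at its promoter and others further upstream. Whether extra copies of the locus from the transgene raised the signal here could not be decided. The gene bcd lies at 3R:6755842 to 6759466 on the minus strand. Its own promoter peak, at 3R:6759529 to 6759831 with its summit 192 bp upstream, had rank 595 and a signal of 633, with ranks 584 in replicate 1 and 648 in replicate 3. A second, at 3R:6760801 to 6761224, had rank 2416 and a signal of 265. The strongest in the window, at 3R:6762750 to 6763278 with rank 292 and a signal of 895, lay inside the neighbouring gene Ama, 324 bp from its TSS. It ranked 889 in replicate 1 and 156 in replicate 3. The transcribed part of bcd held 0 entries of the pooled relaxed list, which had 12 summits within 15 kb of the gene, a number that 23.2% of protein-coding genes reached or exceeded in regions of that size.

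**Figure D4:**
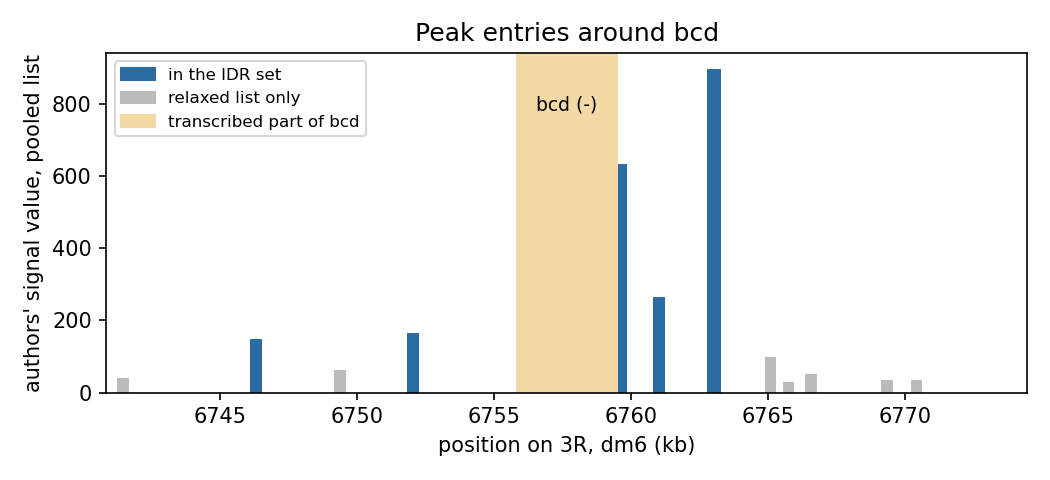
Entries of the pooled relaxed list on 3R around bcd (x axis, dm6 position in kb), drawn to scale in width, with the authors' signal value as height (y axis). Blue entries are in the IDR set, grey ones are not, and the shaded band is the transcribed part of bcd, which holds 0 entries.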

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

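A signal appeared in data outside the comparisons of the report. On dm3, 4 peaks of the IDR set lay on heterochromatic scaffolds outside the named arms, above the limit of 3 that a count of 0 allows. Of these, 3 were on 3LHet and 1 on 2RHet, and the strongest, at 3LHet:2397654 to 2397851, had rank 2135 and a signal of 287. The dm6 IDR set held 0 peaks outside its named arms. The same held for all 30000 entries of the dm6 pooled relaxed list, where that of dm3 had 87 outside. The dm6 lists thus use only the named arms, and their 0 does not show that these sites lack peaks on dm6. Coordinates were not converted between builds, so whether these 4 sites have peaks on the named arms of dm6 was not tested. No explanation of this was tested.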

How the results depend on the processing

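The share of peaks common to both replicates lay above shifts in all 5 alternatives, from 57.5% with all peaks of each list to 72.6% with the N/4 strongest. The shifted shares were 16.4% and 0.670%, so the excess over shifts was smallest with all peaks. The promoter share stayed above shifts in all 4 of its alternatives, from 42.5% without replicate 1 to 57.5% with a TSS within 1000 bp. In all 4 alternatives, 4 of the other words were called more frequent at summits. Against relaxed summits outside the IDR set TATCGATA fell from 6.88 to 3.50 and GGTCACAC from 4.55 to 2.54, and GGTCACAC was 2.73 with the 3027 strongest peaks. When either replicate was left out they ranged from 5.84 to 8.75 and from 3.69 to 5.12. Not called in the report, GAGAGAG passed the exact test as rarer with the 3027 strongest peaks (0.721) and without replicate 1 (0.757), and CAGCTG with the 3027 strongest peaks (0.855).

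The ratio for TAATCC moved to the other side of 1 with the 3027 strongest peaks (1.08, p = 0.355), with 50 bp on either side (1.00, p = 0.805) and against relaxed summits outside the IDR set (1.05, p = 0.363), each time without passing the exact test. It ranged from 0.983 to 1.11 when either replicate was left out. TAAKCY gave 1.23, 200 bp on either side 0.870 and TAATCCC 0.810, which all passed the threshold of 0.05, the first above 1 and the others below. The cause was not tested. CAGCTG ranged from 0.904 to 1.06 when either replicate was left out.

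The number of lists called as enriched, 2 in the report, was 1 with a summit within 1 kb of a TSS, 1 with the nearest TSS only, 3 with the 3027 strongest peaks, 3 with all entries of the pooled relaxed list, and from 1 to 2 when either replicate was left out. Ribosomal protein genes were called each time, but their ratio of 2.67 became 4.37 with a summit within 1 kb of a TSS, 4.57 with the nearest TSS only and 1.38 with all entries of the pooled relaxed list. The E(spl) complex was not called against runs of neighbouring genes (ratio 2.72), an alternative chosen after seeing the data, nor odorant receptor genes with all entries of the pooled relaxed list (0.852). Ratios of observed to expected that turned to the other side of 1 belonged to lists not called in the report, and all but 1 stayed uncalled. With the nearest TSS only they were Bicoid targets (1.61), pair-rule (2.36), segment polarity (1.16), dorsoventral (1.25), germ cells (0.912), muscle (1.29) and neuroblasts (1.16). With no matching they were dorsoventral (1.15), muscle (1.2) and trachea and epidermis (1.31). With the 3027 strongest peaks they were homeotic (0.797), muscle (1.19) and gut (0.715), and with a summit within 1 kb of a TSS homeotic (0.305). When either replicate was left out, dorsoventral genes ranged from 0.876 to 1.21, homeotic genes from 0.95 to 1.34 and heat shock genes from 0.957 to 1.16. With all entries of the pooled relaxed list, also chosen after seeing the data, they were pair-rule (1.21), dorsoventral (1.07), muscle (1.09), neurons (1.02), gut (0.998), heat shock (0.610) and cuticle proteins (1.26), of which cuticle proteins passed the permutation test (adjusted p = 0.015). The cause was not tested. Gustatory receptor genes passed the permutation test for fewer peaks with a summit within 1 kb of a TSS (0.146), the nearest TSS only (0.330), no matching (0.599) and without replicate 1 (0.483). Cuticle protein genes passed it with a summit within 1 kb of a TSS (0.140), the 3027 strongest peaks (0.398), no matching (0.514) and without either replicate (0.455 to 0.459). Chorion genes, with 0 peaks, passed it with no matching. Depth is unknown, so which weak peaks depth kept out could not be assessed. No paired analysis was possible because the design has 1 group.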

Other observations

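The words with the highest excess at summits, among those of 8 bases present in at least 50 peaks, were CAGTGTAG (2.11% of summit windows, 0.273% of flanks, ratio 7.76) and CACTGAGA (3.88%, 0.504%, ratio 7.70), ahead of TATCGATA (6.88). Both promoter words of the report were concentrated near TSSs. TATCGATA occurred in 7.30% of summits within 500 bp of a TSS, a ratio of 14.9 to their flanks, and in 0.427% of summits over 1 kb away, a ratio of 1.05. GGTCACAC occurred in 5.09% of the former, a ratio of 7.25, and also in 0.427% of the latter, a ratio of 1.47.

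The dm6 arms were cut into stretches of 100 kb. The stretch with the most summits, 3R:16200001 to 16300000, held 24 and includes tara and gish. Next came 3L:11300001 to 11400000 with 23, which includes CG6163, and 3L:700001 to 800000 with 21, which includes emc. The genes with the most summits in their window were kirre (22 in 399 kb), CG1677 (21 in 130 kb), shn (18 in 63.3 kb), ush (18 in 69.3 kb) and tara (15 in 39.7 kb). Annotated transposons held 15 summits (0.248%), against 5.77% ± 0.618 (SD) over 200 shifts. How well reads map to transposons was not assessed, so these values do not show a lack of binding there. These regions were chosen after their values were seen, and whether summits cluster more than by chance was not tested.

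Predictions for the tests in the following paragraphs were written before their results were seen, except for the coding exon test of replicate 3 and the composition tests of TATCGATA and GGTCACAC, which were chosen after a first look at frequent words. The first pattern is the lack of an excess of TAATCC. If Bicoid sites lay in the weaker entries below the IDR threshold, the 22918 pooled entries outside the set would hold the word more often than their flanks, but the ratio was 0.942 (exact test, p = 0.79). These entries also hold background, so Bicoid sites in a small part of them would not show. If promoter peaks diluted Bicoid sites in distal peaks, summits over 1 kb from any TSS would hold it, but their ratio was 0.888 (exact test, p = 0.271, 2575 peaks). Whether 1 of the 2 libraries is another sample cannot be told apart, since the larger ratio of the peaks found in a single replicate, 1.15 in replicate 1 (exact test, p = 0.575), fell between the bounds of 1.1 and 1.2 set beforehand, and a wrong label of both libraries was not tested. The age range of 0 to 24 hours, in which cells with Bicoid may be few, also stays open and was not tested, as the labels give both libraries the same age.

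The second pattern is the excess of other words at summits. Base composition may account for TATAAA and TAATTA, which fell in the lower part of all words of their own composition, at 66.7% and 100% of the ranking from the top, with family medians of 1.68 and 1.69. It does not account for TATCGATA or GGTCACAC, which ranked first among 592 and 1680 words of their composition, at 0.169% and 0.0595% of the ranking. The family medians were 1.37 and 0.688. No biological explanation was tested, since the design has 1 group.

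The third pattern is that strong peaks of replicate 1 alone lay near TSSs and those of replicate 3 alone away from them. Their windows differed in AT share, 60.3% ± 7.95 (SD) in replicate 1 and 64.7% ± 6.95 in replicate 3, so a GC bias that differs between the libraries was tested. Within 5 strata of AT share the pooled Mantel-Haenszel odds ratio was 5.57 (95% interval 4.77 to 6.50, which treats peaks as independent), against 6.34 without strata. The split thus remained among windows of similar AT share. The strata matched the summit windows only, and flanks of IDR peaks also differed by location. Their AT share was 55.5% ± 9.82 (SD) for near-TSS summits and 59.4% ± 8.38 for summits over 1 kb from any TSS. The test therefore cannot decide whether such a bias is the whole cause. The odds ratio was not constant, at 6.83 in the least AT-rich stratum, 7.99 in the next and 3.52 in the most AT-rich. Background of the kind in the weaker entries would at least match the coding exon share of the pooled entries outside the IDR set. That share was 4.81% (Wilson 95% interval 4.54 to 5.10). The peaks of replicate 3 alone had 0.382% (0.185 to 0.786), lower than predicted. This bound replaced a first one of 5% after both shares had been seen, so no conclusion is drawn from it. The AT share of those pooled entries was also lower, at 57.5% ± 8.80 (SD). Their near-TSS share was close to that of replicate 3 alone, 20.3% against 18.8%. Unspecific signal at sites that also attract real peaks was not tested. A difference in embryo ages within the collections, or in depth, may underlie it and was not tested.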
